A study of Mus musculus with 10 samples.

How the data were processed

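Poly(A)+ RNA of bone-marrow-derived macrophages was sequenced strand-specifically as 100-bp paired-end reads, with 20 M reads planned per library, per the labels. The series holds 10 libraries, 5 from control mice and 5 from hWDFY3 KI/KI mice, and the groups were taken from the labels. The submitters' processing notes name Salmon 1.6.0, MultiQC and DESeq2 1.34.0, and the genome builds GRCm39 and mm10 without their roles. How Salmon was run, whether it used the strand, the annotation release and how transcripts were summed to genes are not given in the sources used here. The first deposited table holds estimated counts per Ensembl gene, which are not all whole and sum to a different total in each library. The second deposited table holds log2 values on the regularized-log scale, as its name and the DESeq2 of the processing notes tell. It has 14492 rows for 14409 gene IDs, and the lowest total count of a gene in it is 10, while 16896 genes of the count table reach that total, so it was made with a further selection that is not given in the sources used here.

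Estimated counts were rounded to whole numbers. Gene symbols came from GENCODE M21 and the symbol column of the log2 table, which together named 51510 of 54307 gene IDs, 51482 of them in M21. Genes without a symbol took at most 0.00348% of a library's counts and were kept under their ID. Coordinates are those of GENCODE M21 (GRCm38) and were assigned by gene ID to 12394 of the tested genes. The files themselves carry no coordinates, and none were converted between builds. Pairs of libraries of 1 group differed by a chi-square of 9.00 to 52.4 per gene, so no library appeared to be a copy of another in its group. Pairs of a control and a knock-in library were not compared in this way.

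The main test was edgeR 4.0.16 (R 4.3.3) with TMM factors, filterByExpr at its defaults (minimum count 10, minimum total 15), robust dispersion estimation and the quasi-likelihood F-test for genotype over all 10 libraries, without covariates. The Benjamini-Hochberg adjusted p was taken over the 12411 tested genes, and the threshold was 0.05. The SE of a log2 fold change is its size divided by the square root of F. CPM values use the TMM-scaled library sizes, and log2 CPM values a prior count of 2. The biological coefficient of variation was 15.6%. Wdfy3 was also tested with an exact permutation of its log2 CPM. The 34 gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with a correlation estimated per list, and with fry, adjusting over the lists, and list scores were compared with exact permutation tests. The p of the tests on single genes, of fry and of the permutation tests rests on the spread between libraries labelled as separate mice. In camera at the preset correlation, the members of a list are compared with all other genes. That correlation is not taken from these libraries. The exact binomial and Fisher's exact tests used below count genes, taken as independent, and not mice.

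The choices made before the data were examined were the main test, the gene lists, most alternatives and the rule for the genes named. The rule names Wdfy3, the 12 genes with the largest rise and the 12 with the largest fall among non-overlapping genes with an adjusted p under 0.05 and a mean log2 CPM of at least 1 (predicted genes left out), up to 4 called members of each list or, for lists past the threshold with fewer, the 2 members with the smallest p, the 3 genes with the smallest p each way, and Lyz2 and Gt(ROSA)26Sor as common transgene loci. Where fewer than 12 genes passed, all were named. Other named genes were chosen after their values were seen, namely Rpl30-ps1, Gm42653, Thumpd3, Mertk, Axl, Atg7, Atp6v1e1, Ero1l, Ttll3, Srgap3 and further mitochondrial transcripts. The same holds for Lcn2, the stromal genes Col1a1 and Dcn, Xist and the Y-linked genes, and the genes of the closing section.

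The alternatives were RLE and upper-quartile factors, DESeq2 1.42.0 (Wald test, its own size factors and independent filtering), limma-voom, limma-trend on the deposited log2 values, no filter beyond a total of 1 count, a filter of 1 CPM in 5 libraries, dispersion without robust estimation, a test against a log2 fold change of 0.25, the replicate number as a block, and leaving out each library in turn. Added after seeing the data were a fit without the 3 libraries with the most stromal RNA, the stromal marker score as a covariate, and counts that were not rounded. Libraries are named by the replicate number in the labels, which is not said to pair mice.

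The tests were first tested on simulated data with the means and library sizes of these libraries and 12411 genes. Only genes with a mean of at least 1 CPM were changed, so recovery of lower genes was not tested. Genes were drawn independently, so differences between libraries that many genes share were not simulated. For the comparison of knock-in with control, edgeR recovered 20% of 50 genes changed 1.25-fold, 66% of 50 changed 1.5-fold, 84% of 50 changed 2-fold and 98% of 50 changed 4-fold, with 5 false calls. DESeq2 recovered 34%, 72%, 98% and 100%, with 22 false calls. With 5 libraries of 14.6 to 36.4 M counts per group, most changes of 1.25-fold therefore stayed below the threshold in the simulation. A count of 0 allows up to 3 counts in a library, and such limits cover counting error only. Close copies of the 4 called genes outside the region of Gt(ROSA)26Sor were searched with blastn 2.17.0 among the transcripts of GENCODE M21, at 90% identity over at least 100 bases. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Sequence reads, splice forms and the human WDFY3 transcript were not analysed here.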

Results

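RNA was sequenced from macrophages grown out of mouse bone marrow (bone-marrow-derived macrophages), which were differentiated in L-929-conditioned medium and harvested at day 7. The 10 libraries fall into 2 groups of 5. The control group came from wild-type mice, and the other group came from mice carrying the hWDFY3 knock-in on both alleles (KI/KI). WDFY3, also called ALFY, is a large scaffold protein with BEACH and FYVE domains that acts in selective autophagy. The comparison asks how overexpression of WDFY3 changes the macrophage transcriptome. All mice are labelled male and 6 to 8 weeks old, and each library is labelled as a separate mouse. The control libraries held 21.2, 22.6, 16.5, 36.4 and 14.6 M estimated counts, and the knock-in libraries held 20.5, 15.2, 22.9, 20.4 and 20.98 M, in the order of their replicate numbers. Of 54307 genes in the count table, 12411 were expressed strongly enough to be tested. Levels are given as CPM, counts scaled to a common library size, with the mean ± SD over 5 libraries unless stated otherwise, and fold changes as fitted log2 values ± SE.

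The mouse gene Wdfy3 (ENSMUSG00000043940, chromosome 5, 101832956 to 102069921 in GRCm38, minus strand) was measured at 110 ± 9.83 CPM in the controls and 120 ± 6.19 CPM in the knock-in macrophages. The log2 fold change was 0.13 ± 0.066, with an interval of 2 SE from -0.0069 to 0.26. All 5 knock-in libraries lay above the control median, but the groups overlapped. The difference did not pass the test in edgeR (adjusted p = 0.811, unadjusted p = 0.0807), and an exact 2-sided permutation test over all assignments of the libraries gave p = 0.0952. The table counts mouse genes, so the human transcript itself was not measured here, and how reads of human WDFY3 were assigned is not known. This value therefore checks neither the genotype labels nor the degree of overexpression.

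**Figure D1:**
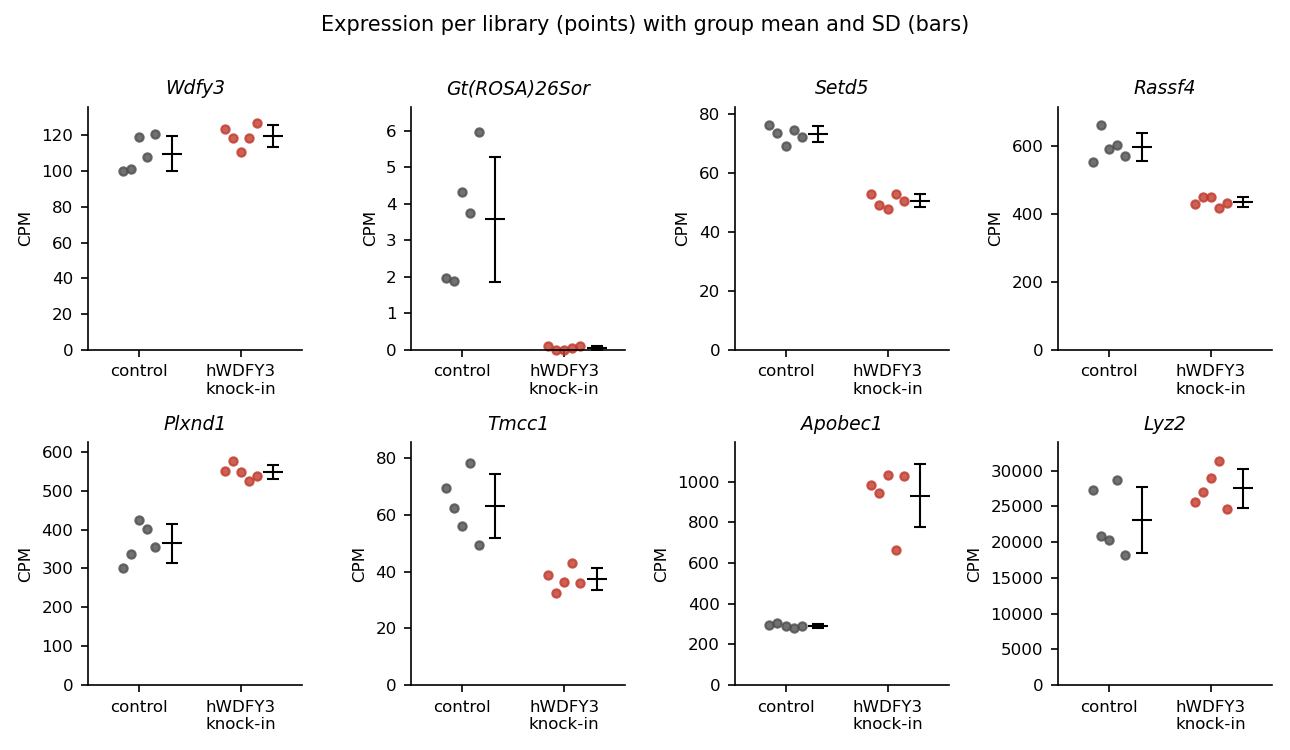
Expression in CPM (y axes, linear, from 0) of 8 genes in the 5 control (grey) and 5 hWDFY3 knock-in libraries (red); each point is a library, and the bars show the group mean and SD. Gt(ROSA)26Sor is near 0 in the knock-in libraries, Setd5, Rassf4, Plxnd1, Tmcc1 and Apobec1 separate the groups without overlap, and the groups overlap for Wdfy3 and Lyz2.

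Apobec1, the cytidine deaminase that edits Apob mRNA, rose 3.20-fold from 291 ± 9.81 to 932 ± 154 CPM (log2 1.68 ± 0.11, adjusted p = 1.28e-05). Plxnd1, a semaphorin receptor, rose from 364 ± 49.5 to 548 ± 18.5 CPM (log2 0.59 ± 0.083, adjusted p = 0.0154). Gt(ROSA)26Sor, the non-coding RNA of a locus widely used for knock-in alleles, fell from 3.58 ± 1.72 to 0.0489 ± 0.0483 CPM (log2 -5.98 ± 0.56, adjusted p = 4.75e-04). Its neighbour Setd5, a SET-domain protein, fell from 73.1 ± 2.68 to 50.5 ± 2.29 CPM (log2 -0.53 ± 0.049, adjusted p = 4.75e-04). Rassf4, of the Ras-association domain family, fell from 597 ± 41.4 to 436 ± 13.97 CPM (log2 -0.45 ± 0.056, adjusted p = 0.00493), and Tmcc1, a membrane protein of the endoplasmic reticulum, fell from 63.2 ± 11.4 to 37.3 ± 3.90 CPM (log2 -0.76 ± 0.12, adjusted p = 0.0390).

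These 6 genes lie on chromosome 6 (GRCm38). Gt(ROSA)26Sor (ENSMUSG00000086429) spans 113067428 to 113077333 on the minus strand, and Setd5 (ENSMUSG00000034269) spans 113077365 to 113153435 on the plus strand, 0.032 kb away. Plxnd1 (ENSMUSG00000030123) starts at 115954811, Tmcc1 (ENSMUSG00000030126) at 116018611, Rassf4 (ENSMUSG00000042129) at 116633008 and Apobec1 (ENSMUSG00000040613) at 122577792. Gt(ROSA)26Sor had 40, 44, 72, 132 and 92 counts in the control libraries and 2, 0, 0, 1 and 2 in the knock-in libraries, so its fitted fold rests on few counts. In a search of both strands, 148 bases of its transcript matched Thumpd3, whose annotated span overlaps it, with full identity. Gt(ROSA)26Sor is annotated as antisense, so the match may lie on the opposite strand. Whether the quantification used the strand is not known. Unless it did and the strands differ, some of the reads of Gt(ROSA)26Sor cannot be placed with certainty. Thumpd3 itself was at 35.7 ± 5.59 and 34.2 ± 3.26 CPM (adjusted p = 0.932). Within 10 Mb of Gt(ROSA)26Sor, a distance chosen after the positions were seen, 98 genes were tested, which is 0.791% of the tested genes with a position. Of the 10 called genes, 6 lay there (exact binomial p = 4.99e-11). That p counts Gt(ROSA)26Sor itself as a hit, takes neighbouring genes as independent and leaves the choice of distance out of account.

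**Figure D2:**
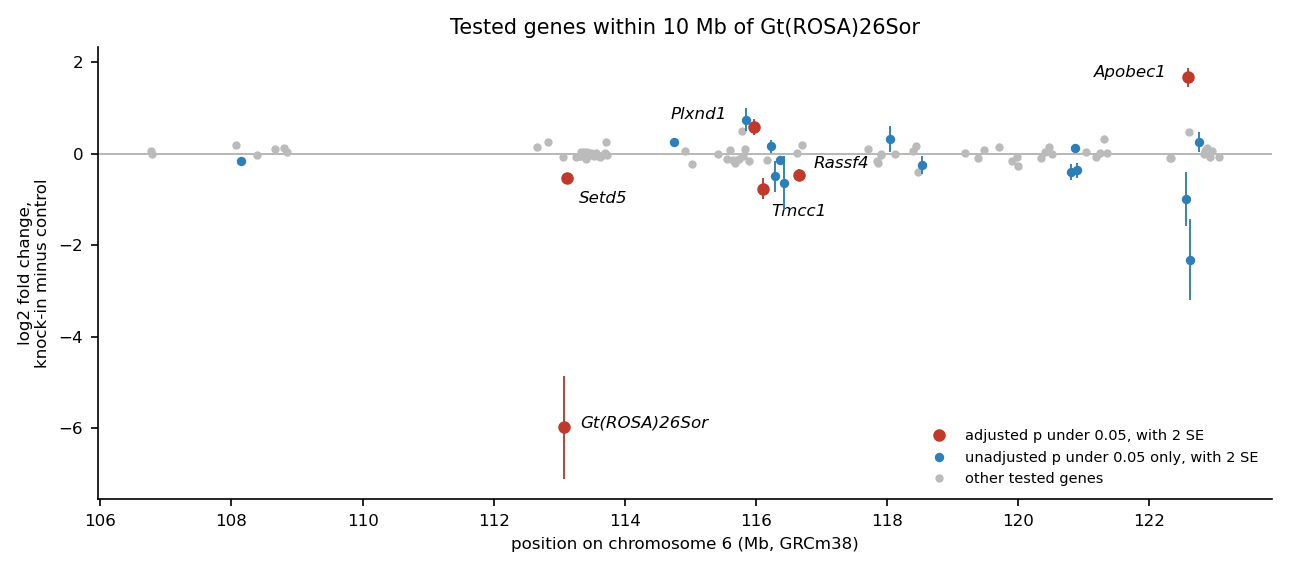
Fitted log2 fold change (y axis, knock-in minus control) against position on chromosome 6 in Mb (x axis, GRCm38) for the 98 tested genes within 10 Mb of Gt(ROSA)26Sor; red points passed the adjusted threshold, blue points had an unadjusted p under 0.05 only, and bars are 2 SE. The 6 red points are 2 genes that rose and 4 that fell, from Gt(ROSA)26Sor at -5.98 to Apobec1 at 1.68.

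The remaining 4 called genes had low counts and are annotated as a lincRNA, a processed pseudogene and, for Gm42923 and Gm42653, as transcripts whose coding status is not settled (biotype TEC). Gm42923 (ENSMUSG00000105134, chromosome 3, 37392206 to 37395101) rose from 1.38 ± 0.559 to 5.63 ± 0.479 CPM (adjusted p = 0.0048), and Gm42653 (ENSMUSG00000106549, chromosome 5, 70561265 to 70564103) rose from 0.730 ± 0.577 to 5.17 ± 0.709 CPM (adjusted p = 0.0372). Rpl30-ps1 (ENSMUSG00000057696), a processed pseudogene at 38376807 on chromosome 6, rose from 0.197 ± 0.149 to 1.88 ± 0.749 CPM (adjusted p = 0.0183). The lincRNA Gm45184 (ENSMUSG00000108483, chromosome 7, 127434422 to 127439392) fell from 2.24 ± 0.864 to 0.0605 ± 0.0911 CPM (adjusted p = 0.00481). Each shares sequence with other annotated transcripts, so some of their reads may be divided and the values are uncertain. Rpl30-ps1 and Gm42653 have close copies, with a longest match of 99.4% identity over all 348 bases and of 97.6% over 2599 of 2839 bases. For Gm42923 and Gm45184 the longest match covered only a part of the transcript, at 92.8% over 470 of 2896 bases and 90.4% over 197 of 955 bases. Matches of at least 100 bases at 90% identity were found in 36 genes for Gm42923 and in 430 for Gm45184. Rpl30-ps1 and Gm42653 are outside the rule for named genes and were named after their values were seen. Rpl30-ps1 lost its call without control 1, control 2, knock-in 1, knock-in 2 or knock-in 3 (adjusted p from 0.0718 to 0.118) and in limma-voom (0.0583), and Gm42653 without control 2, control 4, knock-in 1, knock-in 2, knock-in 3 or knock-in 5 (0.0608 to 0.213) and without a filter on low counts (0.130).

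In all, 10 genes passed an adjusted p under 0.05 in edgeR's quasi-likelihood test, 5 higher and 5 lower in the knock-in macrophages. An unadjusted p under 0.05 was found for 771 genes (6.21%), where 620.55 would be expected by chance. Of 100 splits of the 10 libraries into groups of 5, the real one included, 30 gave at least 771 such genes, and another split gave 1748. An excess of this size is therefore common among groupings of these libraries. The groups did not overlap for any of the 10 called genes. Over all tested genes 164 (1.32%) did not overlap, where chance gives 0.794%. Apobec1, Setd5, Gt(ROSA)26Sor, Rassf4, Gm45184 and Gm42923 kept their calls in each of the 10 fits that left out 1 library. Plxnd1 lost its call without control 2 (adjusted p = 0.0789) or knock-in 1, 2 or 3 (0.0665 to 0.0799), and Tmcc1 without control 1, 2 or 3 or knock-in 1, 2, 3 or 5 (0.0675 to 0.185), without a filter on low counts (0.130) and in limma-trend on the deposited log2 values (0.521). DESeq2 called 52 genes, 34 higher and 18 lower, including all 10, and leaving out the 3 libraries with the most stromal RNA, a choice made after the data were seen, gave 38 genes, 23 higher and 15 lower, again including all 10.

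Lyz2, the macrophage lysozyme gene whose locus often carries myeloid transgenes, was measured at 23060 ± 4636 CPM in the controls and 27539 ± 2712 CPM in the knock-in macrophages (log2 0.26 ± 0.12, adjusted p = 0.799). Without the 3 libraries with the most stromal RNA the log2 difference was 0.43 (adjusted p = 0.0412, with a range from 0.0412 to 0.987 over the alternatives).

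Among 34 gene lists fixed before the data were examined, sterol synthesis, the transcripts of the mitochondrial genome and proliferation were shifted up against all other genes in camera with a preset correlation. All 25 tested sterol synthesis and uptake genes had a positive log2 fold change (median 0.17, adjusted p = 3.29e-05, and adjusted p = 0.660 with an estimated correlation). Hmgcs1, which makes HMG-CoA, was at 68.5 ± 4.40 and 85.6 ± 17.5 CPM (log2 0.32 ± 0.12), and Srebf2, the transcription factor of the pathway, was at 111 ± 15.6 and 129 ± 13.7 CPM (log2 0.21 ± 0.098). Of the proliferation genes, 31 of 36 were positive (median 0.12, adjusted p = 1.16e-04, and adjusted p = 0.792 with an estimated correlation). Pclaf, a PCNA-binding protein, was at 23.6 ± 3.53 and 29.8 ± 3.39 CPM, and cyclin B1 (Ccnb1) at 18.9 ± 2.26 and 22.3 ± 3.56 CPM. No member of either list passed on its own, whether over all genes or adjusted over the list alone (0 genes each). The sterol list lost its call without knock-in 5 (adjusted p = 0.0560), and the proliferation list with the stromal marker score as a covariate (adjusted p = 0.0563), but it kept its call without the 3 libraries with the most stromal RNA (0.0123). The mean log2 CPM of the proliferation list was lowest in those libraries, control 1, control 4 and knock-in 4 (4.58, 4.58 and 4.55), and 4.74 to 5.01 in the other 7.

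Of the transcripts of the mitochondrial genome, 14 of 15 were positive (median 0.15, adjusted p = 1.02e-04, and adjusted p = 0.534 with an estimated correlation). mt-Nd5, a subunit of complex I, was at 3132 ± 264 and 3671 ± 123 CPM (log2 0.23 ± 0.064), and mt-Nd6, the exception, was at 9.03 ± 1.87 and 6.31 ± 0.767 CPM (log2 -0.52 ± 0.15). Adjusted over the list alone, 5 members passed (mt-Nd5, mt-Nd6, mt-Atp6, mt-Nd4 and mt-Atp8), and 0 passed over all genes. The mitochondrial genome took 5.34 to 6.02% of the counts in the control libraries and 5.99 to 6.30% in the knock-in libraries. Within each genotype the mean log2 CPM of this list was highest in the libraries with the most stromal RNA, at 10.76 and 10.77 in controls 1 and 4 against 10.48 to 10.59 in the other controls, and at 10.86 in knock-in 4 against 10.68 to 10.81. The list kept its call without these 3 libraries (adjusted p = 8.43e-07) and with the stromal marker score as a covariate (3.10e-08). The nuclear genes of the respiratory chain and ATP synthase went the other way, with 33 of 40 negative (median -0.052, adjusted p = 7.05e-04, and adjusted p = 0.627 with an estimated correlation). Ndufa4 was at 86.7 ± 5.51 and 76.8 ± 3.8 CPM, and cytochrome c (Cycs) at 47.2 ± 4.52 and 40.8 ± 3.11 CPM. The mean of this list was also highest within each genotype in control 1, control 4 and knock-in 4 (6.26, 6.21 and 6.16). It lost its call without the 3 libraries with the most stromal RNA (adjusted p = 0.150), and 0 of its members passed adjusted over the list alone.

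NRF2 targets and antioxidant genes were shifted down, with 21 of 25 negative (median -0.19, adjusted p = 9.86e-05, and adjusted p = 0.645 with an estimated correlation). Gclc, which catalyses the first step of glutathione synthesis, was at 58.2 ± 3.49 and 50.1 ± 4.64 CPM (log2 -0.22 ± 0.069), whereas Gpx1, a glutathione peroxidase, was at 396 ± 42.0 and 467 ± 18.2 CPM (log2 0.24 ± 0.070). The mean log2 CPM of the NRF2 list was highest in control 1, control 4 and knock-in 4, the libraries with the most stromal RNA (8.48, 8.46 and 8.41). In controls 2, 3 and 5 it was 8.14, 8.28 and 8.15, which overlapped knock-in 1 and 2 at 8.19 and 8.16, while knock-in 3 and 5 were at 8.00 and 7.89. The list kept its call without those 3 libraries and with the stromal marker score as a covariate. In the list of inflammatory cytokines and NF-kB targets 19 of 28 members were negative (median -0.075, adjusted p = 0.0254, and adjusted p = 0.534 with an estimated correlation). The mean log2 CPM of this list was 3.46, 3.37, 3.43, 3.59 and 3.32 in controls 1 to 5, in the same order as the neutrophil markers (3.91, 2.34, 2.84, 4.27 and 1.93). In knock-in 1 to 5 it was 3.09, 3.55, 3.16, 3.38 and 3.04, with knock-in 5, 1 and 3 lowest as for the neutrophil markers (1.93, 2.42, 2.16, 3.13 and 1.26). Lcn2 belongs to both lists. The members of the inflammatory list with the smallest p were Il1rn, which encodes the interleukin-1 receptor antagonist and restrains inflammation, at 104 ± 15.6 and 66.7 ± 10.7 CPM (log2 -0.64 ± 0.13, adjusted p = 0.196), and Sod2, a mitochondrial superoxide dismutase, at 59.9 ± 3.91 and 54.7 ± 2.38 CPM. Adjusted over the list alone, 1 inflammatory gene (Il1rn) and 0 antioxidant genes passed, and DESeq2 called Il1rn over all genes (adjusted p = 4.90e-04, with a range from 4.90e-04 to 0.547 over the alternatives). The inflammatory list lost its call under the stricter filter on low counts (adjusted p = 0.0821) and without control 3, knock-in 1, knock-in 3 or knock-in 5 (0.0633 to 0.115).

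The BEACH-domain and related WDFY family without Wdfy3 was shifted up, with 8 of 9 positive (median 0.064, adjusted p = 0.0492, and adjusted p = 0.534 with an estimated correlation). Nbeal1 was at 20.4 ± 1.69 and 23.01 ± 2.05 CPM, and Lyst, the lysosomal trafficking regulator, at 165 ± 13.05 and 182 ± 15.5 CPM, and 0 members passed adjusted over the list alone. This call was lost in most fits that left out 1 library (without control 1, 3 or 4 or knock-in 1, 2, 4 or 5, adjusted p from 0.0624 to 0.118), with the stromal score as a covariate (0.135) and without the 3 libraries with the most stromal RNA (0.309). The list of genes around Gt(ROSA)26Sor, which holds that gene itself, passed as lower (adjusted p = 0.00127, and adjusted p = 0.243 with an estimated correlation). Of its 21 tested members 12 were negative, with a median of -0.031, quartiles of -0.060 and 0.027 and a mean of -0.31. Its 2 called members are Gt(ROSA)26Sor and Setd5, also the 2 genes called adjusted over the list alone. The fold changes of the others ran from -0.12 for Ttll3 to 0.25 for Srgap3. The list tests were not run without Gt(ROSA)26Sor and Setd5, so the call does not show a shift of the other members. With a correlation estimated per list, 0 of the 34 lists passed in camera and 1 had an unadjusted p under 0.05. fry, which tests whether a list's genes move on balance in 1 direction, called 1 list. This was the list around Gt(ROSA)26Sor (adjusted p = 0.0400), again with Gt(ROSA)26Sor and Setd5 in it.

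**Figure D3:**
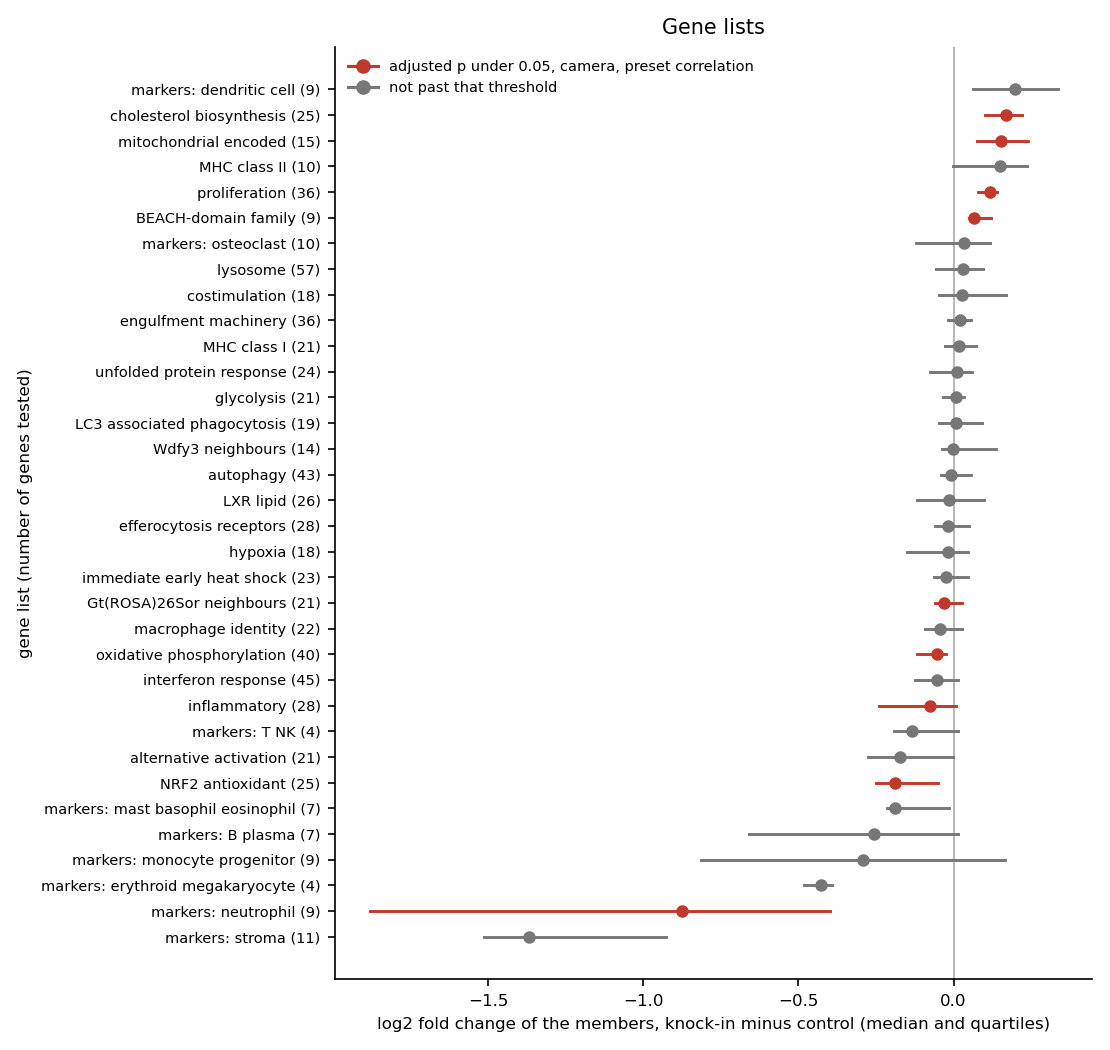
Median (points) and quartiles (lines) of the members' log2 fold change, knock-in minus control (x axis), for each of the 34 gene lists (y axis, number of genes tested in parentheses), in red where camera with a preset correlation gave an adjusted p under 0.05. The 9 red lists have medians from -0.88 for the neutrophil markers to 0.17 for sterol synthesis, and 0 of them passed with an estimated correlation.

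Genes for the recognition and engulfment of apoptotic cells, a process that WDFY3 has been linked to, did not pass the list test. The receptors and bridging molecules had 13 of 28 members positive (median -0.018, adjusted p = 0.977), and the engulfment machinery had 22 of 36 positive (median 0.022, adjusted p = 0.533). Mertk was at 91.2 ± 18.7 and 88.4 ± 22.2 CPM, and Axl at 166 ± 23.6 and 171 ± 19.02 CPM. Autophagy genes had 20 of 43 positive (adjusted p = 0.805), with a median of -0.0070 and a mean of 0.0070, so that median and test differ in sign. LC3-associated phagocytosis had 10 of 19 positive (median 0.0063, adjusted p = 0.542), and lysosomal genes 34 of 57 (median 0.031, adjusted p = 0.626). Adjusted over the list alone, 1 gene passed in each of these 3 lists and 0 in the 2 lists for apoptotic cells. Atg7, the E1-like enzyme of LC3 conjugation, which belongs to both the autophagy and the LC3 list, was at 64.3 ± 3.88 and 76.5 ± 2.96 CPM (log2 0.25 ± 0.054, adjusted p = 0.208 over all genes). Atp6v1e1, a subunit of the lysosomal proton pump, was at 254 ± 32.4 and 193 ± 18.0 CPM (log2 -0.39 ± 0.090, adjusted p = 0.277 over all genes). Both lie on chromosome 6, Atg7 from 114643097 and Atp6v1e1 from 120794305, within the 10 Mb around Gt(ROSA)26Sor. fry's test for change in either direction called 3 lists, the genes around Gt(ROSA)26Sor (adjusted p = 2.59e-08), the mitochondrial transcripts (0.0260) and LC3-associated phagocytosis (0.0326).

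The lists for antigen presentation and activation did not pass either. MHC class II (median 0.15, adjusted p = 0.542), MHC class I (median 0.017, 0.757), costimulation (median 0.026, 0.542), interferon-stimulated genes (median -0.055, 0.268) and alternative activation (median -0.17, 0.104) stayed short of the threshold. So did LXR targets and lipid efflux (median -0.016, 0.533), glycolysis (median 0.0073, 0.977), the unfolded protein response (median 0.011, 0.977), hypoxia (median -0.018, 0.977), macrophage identity (median -0.042, 0.542) and the genes around mouse Wdfy3 (median -0.0030, mean 0.030, 0.709). The immediate-early and heat-shock genes, a sign of handling, had a median of -0.023 and a mean of 0.0039 (adjusted p = 0.809), so their mean and median differ in sign, as they do for the genes around Wdfy3. Adjusted over the list alone, 1 hypoxia gene passed (Ero1l, at 67.4 ± 11.2 and 88.2 ± 2.75 CPM) and 0 genes in the other lists of this group.

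Markers of stromal cells and neutrophils were uneven among libraries of the same genotype. Control 1, control 4 and knock-in 4 held the most collagen and matrix transcripts, with Col1a1 at 35.4, 46.8 and 23.2 CPM against 0.0478 to 7.68 CPM in the other 7 libraries, and Dcn at 23.9, 18.1 and 11.8 CPM. These 3 libraries also had the highest S100a9, a neutrophil calprotectin gene, at 9.56, 14.3 and 3.89 CPM. The first principal component, with 31.3% of the variance, set these 3 libraries apart from the others, and the second, with 15.2%, separated the genotypes. The stromal list had a mean log2 CPM of 1.37 ± 1.83 in the controls and 0.45 ± 1.71 in the knock-in libraries (exact permutation p = 0.421, camera adjusted p = 0.121, median log2 fold change -1.37). The neutrophil list was shifted down, with 9 of 9 markers negative (median -0.88, adjusted p = 0.00127, and adjusted p = 0.534 with an estimated correlation). Lactoferrin (Ltf) was at 1.61 ± 1.68 and 0.363 ± 0.442 CPM, S100a9 was at 5.90 ± 5.79 and 1.57 ± 1.396 CPM, and 0 markers passed adjusted over the list alone. The neutrophil call was lost without control 1 (adjusted p = 0.0540), without control 4 (0.121) and without the 3 libraries together (0.251). The marker lists of monocytes and progenitors (median -0.29, adjusted p = 0.482), dendritic cells (0.20, 0.130), osteoclasts (0.032, 0.542), T and NK cells (-0.13, 0.977), B and plasma cells (-0.26, 0.121), mast cells, basophils and eosinophils (-0.19, 0.542) and erythroid cells and megakaryocytes (-0.43, 0.0904) did not pass, and 0 of their genes passed adjusted over the list alone.

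Xist, the RNA made from the inactive X chromosome of female cells, was at 279 to 405 CPM in the 10 libraries, all of which are labelled male. The Y-linked genes Ddx3y and Eif2s3y had 0 counts in every library, which allows up to 3 counts in each, although their rows are in the table, and Uty and Kdm5d had 47 and 56 counts over all 10 libraries. The expression of these genes goes against the sex label and does not separate the genotypes.

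**Figure D4:**
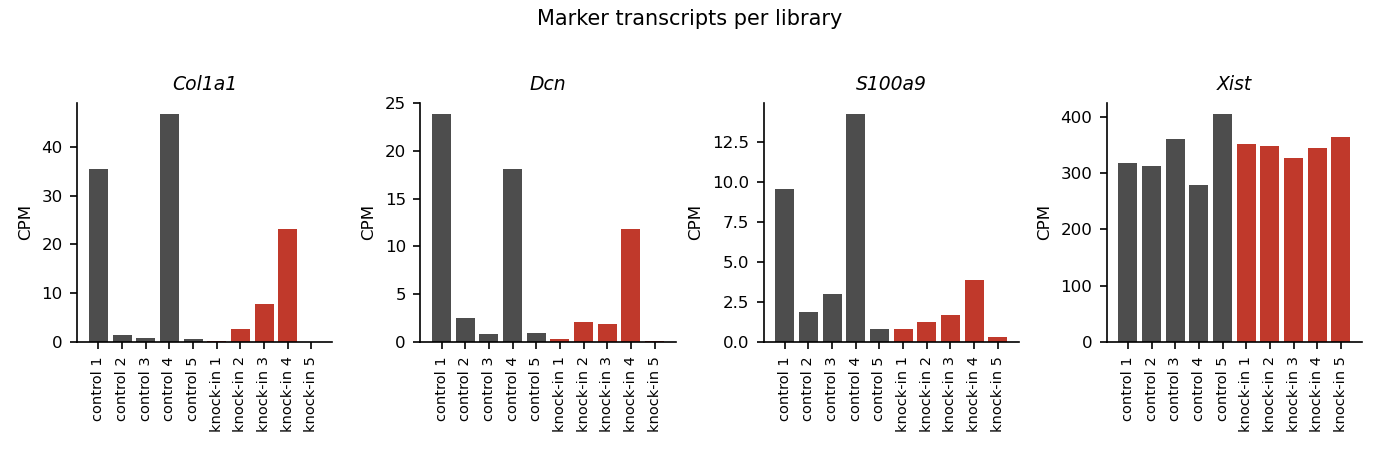
CPM (y axes, linear, from 0) of Col1a1 and Dcn (stroma), S100a9 (neutrophils) and Xist in each control (grey) and knock-in library (red). Control 1, control 4 and knock-in 4 are highest for Col1a1, Dcn and S100a9, while Xist lies between 279 and 405 CPM in all 10 libraries.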

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

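The tests of the region around Gt(ROSA)26Sor, of knock-in 4 and of Xist and the stromal covariate were chosen only after the data were seen. The estimated correlation was planned but was used to weigh the called lists only after its result was seen, and the splits of the libraries were planned.

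Of the called genes, 6 lay within 10 Mb of Gt(ROSA)26Sor, and besides that gene itself all of these were at higher coordinates. Among the other window genes with an unadjusted p under 0.05, only Sumf1 (from 108107028) was at lower coordinates. How the tested genes divide between the sides was not counted. Of the called genes, 4 (Plxnd1, Tmcc1, Rassf4 and Apobec1) lie over 1 Mb and within 10 Mb of the locus, which argues against an effect of an insertion on its direct neighbours only. A transcriptome-wide effect of WDFY3 as the only cause is not expected to gather 6 of 10 called genes among 0.791% of the tested genes. The exact binomial p of 4.99e-11 overstates this. The width was set after the positions were seen, Gt(ROSA)26Sor counts as a hit, and neighbouring genes are taken as independent. An effect of WDFY3 on single genes stays open. Outside the window edgeR called 0 protein-coding genes (lowest adjusted p 0.111 for Cd209c). DESeq2 called at least 32 there, and edgeR without the 3 libraries with the most stromal RNA at least 14. Both are lower limits, since only called genes among the tested genes with a position were counted. These were 49 of 52 called genes for DESeq2 and 35 of 38 without the 3 libraries. Among the genes of the window that were not called, 15 of 92 (16.3%) had an unadjusted p under 0.05 against 745 of 12292 (6.06%) elsewhere, an odds ratio of 3.02 (95% interval 1.604 to 5.33, Fisher's exact p = 4.47e-04), so a candidate explanation is a stretch of DNA from another mouse strain carried along with a knock-in at this locus. No knock-in library exceeded 2.72% of the control mean of Gt(ROSA)26Sor, which fits an allele interrupted on both chromosomes, although the labels do not name the insertion site. Of 100 splits of the 10 libraries into groups of 5, drawn from 126, 3 gave at least 10 called genes, the real split with its 10 among them. The others gave 40 (control 1, control 4 and knock-in 3, 4 and 5 together) and 11 (controls 1 to 4 with knock-in 4), which points to a structure of the samples. At least 771 genes with an unadjusted p under 0.05, the real number, were found in 30 of the 100 splits. A count of 10 called genes was thus uncommon among the splits, but other groupings exceeded it, so chance is not excluded for the number of called genes.

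Knock-in 4 stood apart in Apobec1, at a log2 CPM of 9.37 against 9.89 for the next lowest knock-in library, a gap of 0.802 of the group's range. It is 1 of 5 such gaps of a single library among 128 groups of values, where 6.4 would be expected by chance. On the linear scale knock-in 4 lay at 52.6% of the way from the control mean to the mean of the other 4 knock-in libraries (663 CPM against 291 and 999). In the other 5 called genes of the window it lay at 74.1% (Tmcc1) to 115% (Rassf4). Mbd4 (47.5%), Bid (39.4%) and Dppa3 (61.5%, with a median of 50.5% for the 2 genes over 5 Mb away) passed without knock-in 4 but not in the edgeR test reported over all 10 libraries, a choice that favours genes in which knock-in 4 lies apart, although DESeq2 called all 3 over the 10 libraries. By the same choice, 8 genes outside the window had a median place of 29.8% (Syt12 57.9%, Msln 50.9%). Klhdc7a and Gm42949, also called without knock-in 4, are left out, since they were not among the tested genes with a position. These places therefore leave open whether knock-in 4 carries a linked segment on only 1 chromosome copy.

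Xist was at 279 CPM or more in every library although the mice are labelled male, with 0 counts of Ddx3y and Eif2s3y. Female donors are a candidate explanation. Male donors whose Y transcripts were left out of the quantification would have next to no Xist, and the lowest count of Xist was 5348. Both genotypes show the same pattern, so the comparison stays within 1 apparent sex.

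Of the 9 lists past camera with a preset correlation, 7 kept their call with the stromal marker score as a covariate and 0 kept it with an estimated correlation. Of the 11 stromal markers behind that score, 6 were over 1 CPM in the mean of the other 7 libraries too, and 0 belong to another list. At least 9 lists were called in 31 of 100 splits of the libraries, the real split included, with up to 18 in another split, so chance cannot be excluded for the number of lists.

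Besides Apobec1, 4 sets of values had a single library far from the rest of its group, which makes 5 such gaps among 128 groups of values, against 6.4 expected by chance. Pclaf was highest in control 5 (log2 CPM 4.90 against 4.52 for the next, gap 0.771 of the range). Cycs was highest in control 1 (5.79 against 5.54, gap 0.759). Sod2 was highest in control 4 (6.07 against 5.88, gap 0.850). The T and NK marker list was lowest in control 4 (mean log2 CPM 2.95 against 3.29, gap 0.861).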

How the results depend on the processing

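The fits without the libraries with the most stromal RNA, with a stromal covariate and without rounding were chosen after the data were seen, and all others were planned. The count of called genes was 10 in the test reported and ran from 8 to 12 with RLE or upper-quartile factors, limma-voom, limma-trend on the deposited log2 values, other filters, non-robust dispersion, the stromal covariate and unrounded counts. It rose to 52 with DESeq2 (all 10 shared) and to 38 without the 3 libraries with the most stromal RNA, and fell to 6 against a minimum log2 fold change of 0.25, which is a stricter hypothesis. For DESeq2 the cause was not tested, but it also made more false calls on simulated data. Leaving out 1 library gave 6 to 23 genes, with 6 without control 2 or knock-in 1, 2 or 3 and 23 without knock-in 4, and the cause was not tested. Wdfy3 kept its direction and stayed short of the threshold everywhere (log2 0.028 to 0.16). The 9 lists became 0 with an estimated correlation and 1 with fry, and 7 to 12 under the other alternatives. Of 585 comparisons of 27 named genes across settings, 557 kept their side of the threshold, 26 lost and 2 gained the call, and 0 reversed. Of 171 for the 9 lists, 134 kept it, 37 lost it and 0 reversed. The log2 fold change of a gene moved by a median of at most 0.0058 with RLE factors, upper-quartile factors or DESeq2, which also changes the model.

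The labels do not say whether the replicate numbers pair the samples. Same-numbered libraries correlated at -0.20, 0.027, 0.039, 0.51 and 0.25 after the group means were removed. Only replicates 4 and 5 correlated best with their own number in both directions. These correlations cannot settle the pairing, since control 4 and knock-in 4 are both among the libraries with the most stromal RNA. The replicate block gave 12 genes (10 shared), 12 lists and a Wdfy3 log2 fold change of 0.13. Depth limits genes such as Gt(ROSA)26Sor and Gm45184, whose knock-in libraries hold 0 to 4 counts.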

Other observations

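The tests in this part were chosen after the values were seen, as were the genes named. Mbd4, a DNA glycosylase with a methyl-CpG-binding domain, lies between Gt(ROSA)26Sor and Plxnd1 (chromosome 6, 115840697 to 115853371) and was at 5.56 ± 0.872 and 9.28 ± 1.09 CPM (n = 5 each, log2 0.74 ± 0.12), just short of the threshold in edgeR (adjusted p = 0.0584). Bid, a pro-apoptotic BH3-only protein at 120891930 to 120916853, was at 38.7 ± 3.26 and 30.04 ± 3.04 CPM (adjusted p = 0.212). Both were called over all 10 libraries by DESeq2, and in edgeR without knock-in 4 and without the 3 libraries with the most stromal RNA. Mbd4 was also called over all 10 by limma-voom and by edgeR without the filter on low counts, with the replicate block or with the stromal covariate, and without control 5. Of the genes within 10 Mb of Gt(ROSA)26Sor with an unadjusted p under 0.05 that were not called, 6 were higher and 9 lower in the knock-in libraries.

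Some genes elsewhere were nearly on or off. Npy, which encodes neuropeptide Y (chromosome 6, 49822710 to 49829507), was at 11.2 to 25.2 CPM in the 5 controls and 12.2 CPM in knock-in 4, but at most 0.175 CPM in the other 4 knock-in libraries. Syt12 (chromosome 19, 4445908 to 4477447), a synaptotagmin, was at 1.76 to 3.26 CPM in the controls, 1.13 CPM in knock-in 4 and at most 0.0975 CPM in the others. Cd209c, a C-type lectin gene (chromosome 8, 3940222 to 3954746), was at 0 to 0.784 CPM in the controls and 2.31 to 2.93 CPM in the knock-in libraries. Lilra6, a leukocyte immunoglobulin-like receptor gene on chromosome 7 (3908280 to 3915503) with close paralogs that can share its reads, was at 20.04 to 42.8 CPM in the knock-in libraries, and at 32.5 and 18.0 CPM in controls 1 and 4 but 1.85, 1.44 and 2.34 CPM in controls 2, 3 and 5. None of these 4 genes passed the edgeR test reported over all 10 libraries. Under other settings, Syt12 was called by DESeq2, limma-voom and limma-trend, and Cd209c by DESeq2, limma-trend, and edgeR with the stromal covariate or without control 3. In edgeR, Npy and Syt12 were also called without knock-in 4 and without the 3 libraries with the most stromal RNA, and Lilra6 without those 3 libraries. The 3 libraries are control 1, control 4 and knock-in 4. These settings thus remove the libraries that lay apart from their group, knock-in 4 for Npy and Syt12 and controls 1 and 4 for Lilra6. Such calls are therefore no separate evidence for a difference between the genotypes.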
